A study of Escherichia coli str. K-12 substr. MG1655 with 9 samples.

How the data were processed

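Structure-seq2 libraries of 3 control, 3 DMS and 3 EDC cultures were analysed from 2 deposited files each. Per the labels' protocols, probes were quenched with dithiothreitol, controls received the same quencher, rRNA was depleted, random hexamers primed reverse transcription, and an adapter was ligated to the cDNA end before single-end sequencing. Per the submitters' processing notes, reads were handled with cutadapt 3.5, Bowtie2 2.4.4 and SAMtools 1.16, whose roles and the genome build are not given in the sources used here. The first deposited file holds raw counts of stops at every position of 575 RNAs (1385997 positions), with no normalization. The second deposited file holds a count of reads covering each position, and for DMS replicate 2 it lacks 6 RNAs. Depth per stop was lower in ssrA, which overlaps smpB-ssrA, than in operons without overlap (32.7 against a median of 63.1 nt, control replicate 1). It was also lower in ffs (45.3 nt), which overlaps no entry, and no tRNA gene was checked. The stop files may therefore count a read at each place it aligns and the depth files once. Stops of near-identical or overlapping RNAs, such as tRNA genes and the ssrA and smpB-ssrA entries, are uncertain. Of 1407 gene names 1405 matched the table of the ASM584v2 assembly, which was used for names only.

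Stops were summed per RNA and tested with edgeR 4.0.16 (quasi-likelihood F test, robust, all 9 libraries in 1 fit, group as the only term) under R 4.3.3. TMM factors and library sizes came from non-rRNA stops. CPM are stops scaled to the TMM-adjusted non-rRNA total. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The SE of a log2 fold change, for RNAs and positions, was back-calculated as its size over the square root of the F statistic. It is therefore approximate, above all where a group had few or no stops. For positions the stops at each position were tested in the same way with the log of the RNA's stop total as the offset, for positions with a mean of at least 20 stops, leaving out the first 1 and last 20 positions of an RNA: 18953 positions were kept, 4212 of them in rRNA. A fold against a group with no stop used a floor of 3 stops over the group. Molecular identifiers are not given in the sources used here, so reads may not be separate molecules and floors cover counting error only.

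Gene lists (21, of which 14 had 3 or more measured RNAs) were tested with camera in limma 3.58.1 at a correlation of 0.01, then with an estimated one. Fry, another list test in limma, was run beside it. The lists, tests, alternatives and naming rule were fixed before the data were examined. The rule took, per comparison of RNAs, the 8 largest rises and 8 largest falls past the threshold without overlap between groups and with mean abundance above the median, plus up to 4 members of each list with the smallest p. For positions it took the 3 largest changes past the threshold without overlap per class of RNA, 1 per RNA outside rRNA, and ssrA, rnpB, ffs and ssrS were always described. Lists with under 3 measured RNAs were not tested.

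On simulated data for RNAs in DMS against control (575 RNAs, 200 changed) the fit recovered 32% of 2-fold and 90% of 4-fold changes, with 5.43% false calls. On simulated positions for the same comparison (18953 positions, 200 changed) at the fitted dispersions, whose median was 0.641, it recovered 0% of 2-fold and 0% of 4-fold changes. This first simulation led to 2 more: with larger changes it recovered 36% of 16-fold and 67% of 64-fold changes, and at a dispersion of 0.1 it recovered 4% of 2-fold and 79% of 4-fold changes. In the first, 4.03% of unchanged positions had an unadjusted p under 0.05. The position test therefore recovered none of the rare changes of 4-fold or less at these dispersions.

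Samples share replicate numbers across groups. Deviations of same-numbered libraries correlated at 0.329, 0.235 and 0.514 between DMS and EDC, so the numbers pair those groups on this check from the data. They correlated at 0.272, -0.262 and 0.418 between control and DMS and 0.184, -0.618 and 0.42 between control and EDC, so the numbers do not pair the controls. Controls also correlated with libraries of other numbers, from -0.724 (control replicate 1, EDC replicate 3) to 0.575 (control replicate 2, EDC replicate 3). Replicate numbers do not describe this shared variation. Alternatives were DESeq2 1.42.0 (size factors and Wald test), filters, the block, fits of 2 groups, deposited depth, other offsets, and leaving out each library. Stops by base identity in mRNA, stops at untargeted bases, predicted unpaired against paired bases and reactivity around start codons were planned and not run, because no genome sequence was used here.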

Results

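Reverse transcription stops were counted along 575 RNAs of Escherichia coli K-12 MG1655, a laboratory strain, by Structure-seq2, a sequencing assay in which a chemically modified base halts the reverse transcriptase. Cells in mid-exponential growth at 37 °C received dimethyl sulfate (DMS, 40 mM), the carbodiimide EDC (35 mM) or no probe, and both probes acted for 5 min. DMS methylates unpaired A and C, and EDC reacts with unpaired G and U. Each of the 3 groups had 3 biological replicates, per the series' design text. The RNAs comprised 546 operons, of which 27 hold tRNA genes, 3 rRNAs and 26 other noncoding RNAs. Total stops per library ran from 8822756 to 19527565, and those outside rRNA from 1381534 to 4264347.

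Library makeup varied. The rRNA share was 78.5% ± 5.72 in controls, 82.9% ± 0.369 with DMS and 84.1% ± 0.358 with EDC (SD, n = 3 each), with no test, and control replicate 1, at 84.4%, lay above every DMS and EDC library. A stop was seen at 11.7% to 24.4% of non-rRNA positions in 8 libraries but at 2.09% in DMS replicate 2, where 1% of the positions held 97.5% of the non-rRNA stops. Stops in operons with tRNA genes made up 20.7% ± 1.09 of non-rRNA stops in controls, 21.3% ± 5.04 with DMS and 43.5% ± 10.9 with EDC (SD, n = 3 each).

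The first comparison asked which RNAs gave more or fewer stops after DMS. Of 9 measured RNAs of the OxyR regulon, the peroxide response, 6 were higher in DMS-treated cells (camera adjusted p = 7.35e-08, but adjusted p = 0.182 with an estimated correlation). The glutaredoxin RNA grxA rose from 39.2 ± 6.70 to 451 ± 106 CPM (stops, SD, n = 3 each), a log2 fold change of 3.52 ± 0.35 (SE). The RNA of Dps, a DNA-protecting ferritin-like protein, rose by 3.36 ± 0.39 (SE), and the small RNA oxyS by 4.02 ± 0.88 (SE). Beyond this regulon, marR-marA-marB, which encodes the multidrug resistance regulators, rose by 3.40 ± 0.42 (SE), and fabB, which encodes a fatty acid synthase, by 2.06 ± 0.32 (SE). The trigger factor RNA tig rose by 1.42 ± 0.27 (SE). In edgeR's quasi-likelihood test 18 of 575 RNAs passed an adjusted p of 0.05, 13 higher and 5 lower with DMS, and 133 had an unadjusted p under 0.05. The groups did not overlap in 32% of RNAs, where chance gives 10%. The split into rises and falls depended on the method: 13 and 13 with deposited depth in place of stops, and 32 and 35 in DESeq2.

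In the OxyR list 6 of 9 RNAs rose over all RNAs tested and 9 adjusted over the list alone. The peroxidase operon ahpC-ahpF rose by 1.49 ± 0.32 and the operon holding htpG and hemH by 1.08 ± 0.23 (log2, SE). For yhiR-gor, which includes the glutathione reductase gene, the log2 fold change was 3.75 ± 0.82 (SE), with 13431 CPM in DMS replicate 2 against 1530 and 2013 in the other DMS libraries, and it was 2.07 without that library. Heat shock genes had 3 of 14 RNAs higher: the chaperonin operon groS-groL (1.52 ± 0.28, log2, SE), tesA-ybbO-ybbN (1.02 ± 0.21) and the operon holding htpG and hemH, which is also counted for OxyR. Adjusted over the heat shock list alone, 6 were higher and 1 lower. That list did not pass camera (adjusted p = 0.0695) but did without DMS replicate 2 (0.00828). In the superoxide and multidrug list marR-marA-marB was the only 1 of 9 past the threshold, and zwf stood at 0.83 ± 0.29 and acrA-acrB at 0.51 ± 0.22 (camera adjusted p = 0.0695, and 0.0246 without DMS replicate 2).

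The entry ompC-apbE-ada had a log2 fold change of 0.11 ± 0.23 with DMS (SE, edgeR adjusted p = 0.779), but at 5068 CPM in controls it sums the porin gene ompC with ada, the regulator of methylation repair, so it says nothing of ada alone. None of 11 SOS RNAs passed edgeR's threshold, nor did any adjusted over the list alone: ygaD-recA-recX stood at 0.66 ± 0.26 and dinQ at 1.19 ± 0.50 (camera adjusted p = 0.0931, and 0.027 without DMS replicate 3). Of 3 iron uptake RNAs none passed, and 2 were lower adjusted over the list alone, with fhuF at -2.76 ± 0.65 (edgeR adjusted p = 0.0612, camera adjusted p = 0.0931, and 0.0104 without DMS replicate 2). Among general stress RNAs dps was the 1 of 6 higher, and osmE stood at -2.02 ± 0.86. Of the 19 housekeeping and regulatory RNAs oxyS was the 1 higher, while gcvB, a small RNA that represses amino acid transporters, stood at -1.76 ± 0.56 and ssrA (tmRNA) at 0.87 ± 0.27. Cpx and sigma E envelope stress (camera adjusted p = 0.791 and 0.733), cold shock (0.952), ribosomal proteins (0.918), toxin-antitoxin (0.839), anaerobic respiration (0.478) and amino acid biosynthesis (0.899) had no member called. In fry the lists that passed were OxyR (adjusted p = 0.000963), superoxide and multidrug (0.000696) and anaerobic respiration (0.0137). The 5 RNAs that fell were tomB-hha-maa-ylaC (-2.30 ± 0.47), ygiF-glnE-rfaE-sibE (-1.76 ± 0.36), mlaA, a lipid transport gene (-1.55 ± 0.26), ypaA (-1.51 ± 0.27) and gloB-mltD (-1.36 ± 0.27). The last 2 fell outside the naming rule and were named after their values were seen. Control values of tomB-hha-maa-ylaC, used for DMS and EDC alike, were uneven: 805, 616 and 2225 CPM in replicates 1, 2 and 3. With only control and DMS libraries in the fit 6 RNAs passed. Without control replicates 1, 2 and 3 the count was 11, 9 and 8, and without DMS replicates 1, 2 and 3 it was 9, 22 and 11. Of the 14 called RNAs that the rule named, grxA, dps, marR-marA-marB and fabB passed whichever library was left out, with adjusted p of at most 0.0173, 0.0197, 0.0239 and 0.0317. The call of yhiR-gor ended without any 1 control (adjusted p up to 0.154), that of ahpC-ahpF also without DMS replicate 1 (0.146), and those of oxyS (0.148), tig (0.138) and tesA-ybbO-ybbN (0.148) also without DMS replicates 1 and 3. The operon of htpG and hemH lost its call without any of the 6 libraries (0.148), groS-groL without control replicate 2 or 3 or DMS replicate 1 (0.088), and mlaA without DMS replicate 3 (0.0512). The call of tomB-hha-maa-ylaC held only without control replicate 2 (otherwise up to 0.113) and that of ygiF-glnE-rfaE-sibE only without control replicate 1 (0.121). With the replicate number as a block both these calls ended. So did those of yhiR-gor, oxyS, ahpC-ahpF and the operon of htpG and hemH (edgeR adjusted p up to 0.0523).

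**Figure D1:**
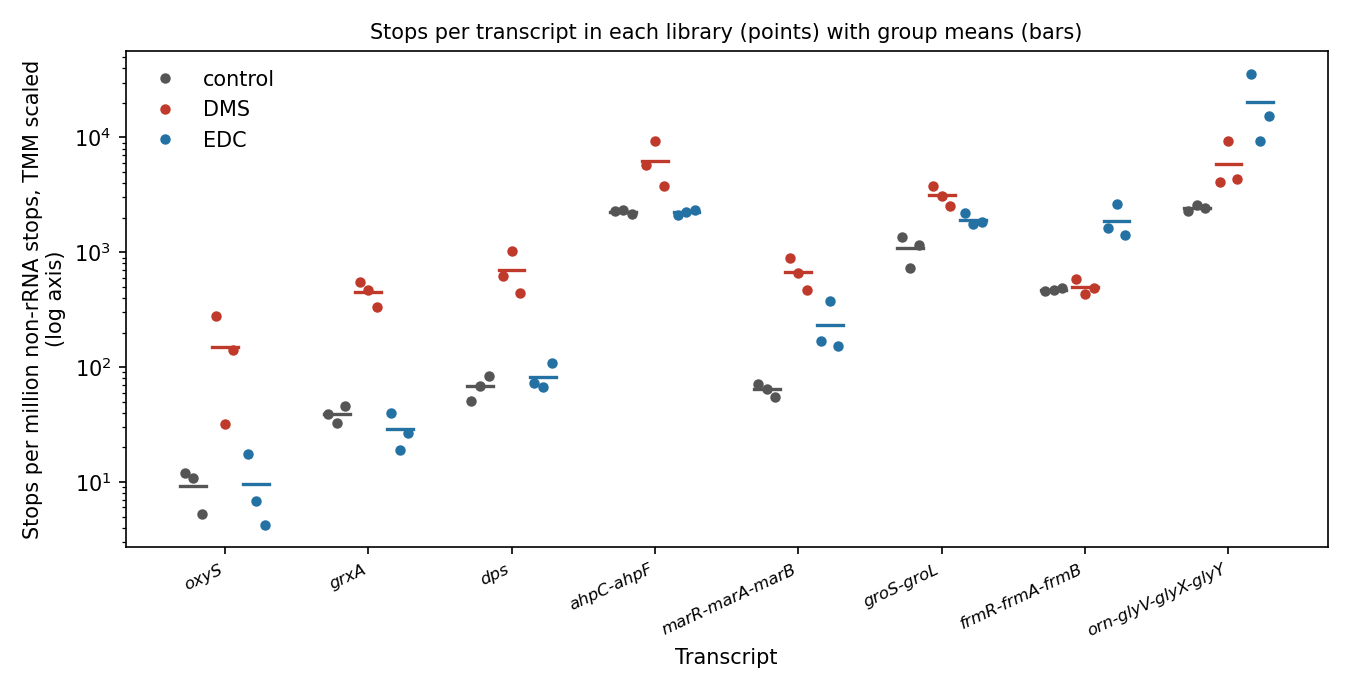
CPM of stops after TMM scaling (log axis) for 8 RNAs, with 1 point per library, bars for group means, and colours for control, DMS and EDC. The 3 DMS points of grxA, dps and marR-marA-marB lie above all control points. The 3 EDC points of frmR-frmA-frmB and orn-glyV-glyX-glyY lie above all control points, as do the 3 DMS points of orn-glyV-glyX-glyY.

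The same question was put to EDC. Operons with tRNA genes were higher: 12 of 27 rose, none fell, and their median log2 fold change was 1.58. The operon orn-glyV-glyX-glyY, with 3 glycine tRNA genes, rose from 2424 ± 162 to 20233 ± 13965 CPM (SD, n = 3 each), or by 3.06 ± 0.54 (log2, SE). Its values with DMS also lay above every control, at 4052, 9351 and 4326 CPM in replicates 1, 2 and 3, though it was not called there. DMS replicate 2 lay above EDC replicate 2, at 9293 CPM. The formaldehyde detoxification operon frmR-frmA-frmB rose by 2.00 ± 0.27 (SE). RNAs of tomB-hha-maa-ylaC, the glycogen gene glgS and the magnesium transporter operon mgtL-mgtA fell. In all, 32 of 575 RNAs passed in edgeR, 20 higher and 12 lower, 94 had an unadjusted p under 0.05, and 25.9% did not overlap between groups (chance gives 10%). Of other RNAs 8 of 548 were higher, and without EDC replicate 1 the calls among tRNA operons went from 12 to 1. A camera test of this class, chosen after its values were seen, gave p = 9.61e-19, and p = 0.0416 with an estimated correlation.

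Further tRNA operons among the largest rises were alaW-alaX (2.79 ± 0.60), metY (2.65 ± 0.53), valU-valX-valY-lysV (2.57 ± 0.46), metZ-metW-metV (2.56 ± 0.52), uvrY-uvrC-pgsA-glyW-cysT-leuZ-yecA (2.45 ± 0.45), ychJ-purU-tyrT-tyrV (2.22 ± 0.31) and asnB-metT-leuW-glnU-glnW-metU-glnV-glnX (2.22 ± 0.49; log2, SE). The tRNA share of every EDC library lay above that of every control, at 32.8% or more against 21.9% or less. Other traits differed as well: 14.7% to 20.9% of all stops lay at position 1 of an RNA in EDC libraries against 25.9% to 33.6% in controls. In EDC replicates 1, 2 and 3 tRNA shares of 54.6%, 32.8% and 43.1% went with a non-rRNA depth over stops of 34.3, 51.9 and 40.8 nt, against 50.5 to 72.3 nt in controls. DMS replicates 1, 2 and 3 also had low values, at 44.6, 30.3 and 43.3 nt. Their tRNA shares of 20.4%, 26.7% and 16.7% lay below those of every EDC library. The largest falls were tomB-hha-maa-ylaC (-2.17 ± 0.47), glgS (-1.82 ± 0.44), mgtL-mgtA (-1.77 ± 0.35), mlaA (-1.47 ± 0.26), the magnesium transporter gene corA (-1.37 ± 0.32), the oligopeptide transporter operon oppA-oppB-oppC-oppD-oppF (-1.26 ± 0.29), the universal stress gene uspA (-1.22 ± 0.23) and efp-ecnA-ecnB-sugE (-0.79 ± 0.19).

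In fry only anaerobic respiration passed with EDC (adjusted p = 0.0476), with none of its RNAs called. None of the 14 fixed lists with 3 or more RNAs passed camera with EDC (0 of 14 with an estimated correlation too), though housekeeping and regulatory RNAs did without control replicate 1 or EDC replicate 3 (adjusted p = 0.0248 and 0.0189). Single members did: marR-marA-marB rose by 1.86 ± 0.40, 1 of 9 in its list, the toxin-antitoxin operon yefM-yoeB-yeeZ-yeeY fell (-1.07 ± 0.24), 1 of 5, and tmRNA rose by 1.35 ± 0.27 as its own entry and by 1.34 ± 0.26 in smpB-ssrA, entries that share reads. Among ribosomal protein RNAs the thrU to rpoC operon, which also carries tRNA genes, was the 1 of 18 higher (1.61 ± 0.34). No member of the OxyR list was called (grxA at -0.44 ± 0.33, dps at 0.28 ± 0.36), nor of the heat shock list (dnaK-dnaJ at 1.40 ± 0.51, groS-groL at 0.83 ± 0.28) or the SOS list (tisB at -0.83 ± 0.55). In general stress bolA stood at -1.39 ± 0.37 and msyB at -1.30 ± 0.37, 0 of 6 over all RNAs and 2 lower adjusted over the list alone. Without control replicates 1, 2 and 3 the count was 6, 1 and 1, and without EDC replicates 1, 2 and 3 it was 4, 15 and 4. With deposited depth in place of stops 17 RNAs passed, and 48 passed, 24 higher and 24 lower, without DMS replicate 2, a library that shares the estimate of spread. DESeq2 called 32 higher and 29 lower. None of the 22 called RNAs that the rule named kept its call whichever library was left out. The calls of frmR-frmA-frmB and ychJ-purU-tyrT-tyrV ended without control replicate 2 or 3 (adjusted p up to 0.0728). The other 7 tRNA operons named among the largest rises, the thrU to rpoC operon and mgtL-mgtA passed only without EDC replicate 2 and mlaA only without control replicate 1 (otherwise up to 0.106). For tomB-hha-maa-ylaC, glgS, corA, the opp operon, uspA, efp-ecnA-ecnB-sugE, yefM-yoeB-yeeZ-yeeY, marR-marA-marB and tmRNA the call ended without any of the 6 libraries, with adjusted p up to 0.189. With the replicate number as a block the calls of tomB-hha-maa-ylaC, glgS, corA, the opp operon and efp-ecnA-ecnB-sugE ended (edgeR adjusted p up to 0.0708). So did those of yefM-yoeB-yeeZ-yeeY, metZ-metW-metV and the thrU to rpoC operon.

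The direct comparison of the reagents found the OxyR RNAs grxA (3.96 ± 0.36) and dps (3.08 ± 0.38) higher with DMS than with EDC. Lower with DMS were frmR-frmA-frmB (-1.91 ± 0.27), the tRNA operons ychJ-purU-tyrT-tyrV (-2.46 ± 0.32), serU (-2.02 ± 0.40) and serV-argV-argY-argZ-argQ-yqaB-yqaA-gshA-luxS (-1.93 ± 0.25), the regulator gene lrhA (-1.30 ± 0.25), and yncJ (-3.44 ± 0.55), named after its value was seen. These 8 of 575 RNAs passed in edgeR, with 119 at an unadjusted p under 0.05 and 27% without overlap (chance gives 10%). In camera 4 lists passed: OxyR (higher with DMS, adjusted p = 1.04e-06), SOS (higher, 0.023), superoxide and multidrug (higher, 0.023) and housekeeping and regulatory RNAs (lower, 0.023). With an estimated correlation these stood at adjusted p = 0.199, 0.455, 0.199 and 0.455. In fry they stood at adjusted p = 0.00575, 0.186, 0.00575 and 0.159. Leaving out 1 library ended the camera calls of all but OxyR, with adjusted p up to 0.171, 0.0845 and 0.0818. Over all RNAs 2 of 9 OxyR members passed, and 8 of 9 adjusted over the list alone; oxyS stood at 3.95 ± 0.89 and ahpC-ahpF at 1.50 ± 0.32. No SOS member passed (tisB at 2.06 ± 0.56, ygaD-recA-recX at 0.66 ± 0.26), and csrB, an RNA that sequesters the regulator CsrA, stood at -1.55 ± 0.44. Without DMS replicate 2, 22 RNAs passed (8 higher, 14 lower), without EDC replicate 2, 18, and in DESeq2 34 were higher and 36 lower. With the replicate number as a block 6 RNAs passed, and the calls of serU and lrhA ended (adjusted p = 0.074). That block covered all 9 libraries, including the controls that the numbers do not pair. It is therefore no paired test of DMS and EDC alone, and the main fit ignores their pairing. The call of serU held only without EDC replicate 2 (otherwise up to 0.149), and that of lrhA ended without DMS replicate 1, EDC replicate 1 or EDC replicate 3 (up to 0.149).

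Single positions were compared next, relative to the stops of the whole RNA in each library, to ask where DMS raised the stop frequency. The largest rises in rRNA lay in 23S rRNA (rrlH), at position 1816 (from 0.0113 ± 0.0053 to 2.13 ± 1.01 stops per 1000 stops of the RNA, SD, n = 3 each), position 2852 (from 0.00875 ± 0.00238 to 1.56 ± 0.852) and position 341 (from 0.0765 ± 0.0388 to 13.5 ± 3.32). Their log2 fold changes were 7.56 ± 0.74, 7.48 ± 0.79 and 7.47 ± 0.69 (SE). Position 341 lies at 226099 on the forward strand in the numbering of the deposited names, whose build is not given in the sources used here. Of 18953 positions tested in edgeR 2298 passed an adjusted p of 0.05, 1597 higher and 701 lower, and 45% did not overlap between groups (chance gives 10%). The balance leaned the other way over these non-overlapping positions, of which 3528 of 8535 were higher, and the median log2 fold change over all positions was -0.18. By class, 321 of 4212 rRNA positions, 192 of 2593 in tRNA operons, 61 of 798 in other noncoding RNAs and 1724 of 11350 in the remaining operons passed. Without DMS replicate 2 these counts were 883, 568, 216 and 4312, and the rRNA split went from 217 higher and 104 lower to 399 higher and 484 lower.

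Outside rRNA the named DMS positions with the steadiest DMS values were position 5901 of the ybgC to lysQ operon, which carries lysine and valine tRNA genes (18.4 ± 1.89 stops per 1000, 8.86 ± 1.19, log2, SE), and position 10537 of the thrU to rpoC operon, with 0 stops in controls and an at least 208.4-fold higher frequency against a floor of 3 stops over the group. Position 161 of rnpB, the RNase P RNA, rose by 5.96 ± 1.07 and position 264 of csrB by 6.26 ± 0.99, and without DMS replicate 2, which held the largest DMS counts, by 4.77 and 5.31. At other positions where DMS replicate 2 held most of the DMS stops the fold rested on it: gcvB position 154 rose by 6.86 ± 1.77 and by 4.64 without that library, and the positions with no control stop in ffh-rpsP-rimM-trmD-rplS (1705), deoC-deoA-deoB-deoD (5340), aceE-aceF-lpd (830) and proB-proA-thrW (3023) were at least 413.1-fold, 295.2-fold, 244.2-fold and 83.7-fold higher. These bounds include that library, without which the fitted log2 fold changes went from 11.01, 10.88, 10.76 and 9.14 to 8.57, 6.10, 7.22 and 6.67. All but the last then lie below the bounds given. In tmRNA 6 positions rose and 4 fell of 173, and in rnpB 13 of 188 rose and none fell. In ssrS (6S RNA) 3 of 88 rose and in ffs (signal recognition particle RNA) none of 30 passed in edgeR, with 4 at an unadjusted p under 0.05. Without DMS replicate 2 these counts were 22 higher and 27 lower in tmRNA, 32 and 2 in rnpB, 8 and 7 in ssrS and 3 and 2 in ffs. Of non-overlapping positions 14 of 56 in tmRNA and 26 of 65 in rnpB were higher. The count of 2298 became 79, 83 and 62 without control replicates 1, 2 and 3 (69, 75 and 59 higher), 1291 without DMS replicate 3 (1170 higher, 121 lower) and 5979 without DMS replicate 2. Without DMS replicate 2 it split into 3270 higher and 2709 lower. It was 122 with only the 2 groups in the fit (119 higher, 3 lower), 202 with the replicate number as a block (182 and 20) and 4978 in DESeq2 (2650 higher, 2328 lower). The 3 named 23S positions, position 10537 of the thrU to rpoC operon and position 5901 of the ybgC to lysQ operon passed whichever library was left out. The csrB call ended without control replicate 1 (adjusted p = 0.052), and those of the other named positions ended without any 1 control (up to 0.147).

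**Figure D2:**
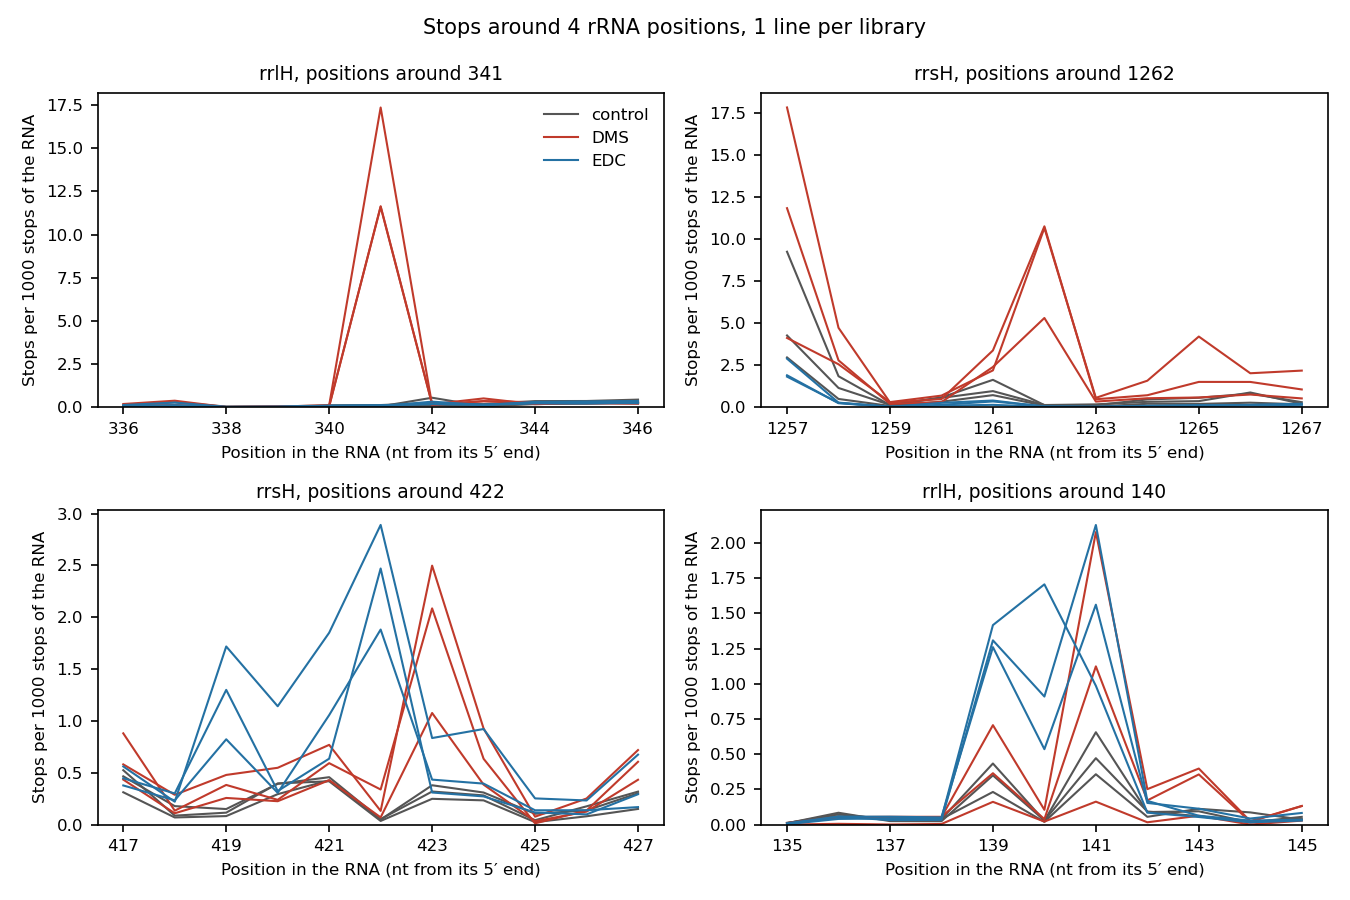
Stops per 1000 stops of the RNA (vertical axis) against position in nt from the 5′ end, for 5 positions either side of 4 named rRNA positions, with 1 line per library. DMS libraries lie above the others at rrlH 341 and rrsH 1262, though DMS replicates 1 and 3 are higher still at rrsH 1257. EDC libraries lie above the others at rrsH 422 and rrlH 140.

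With EDC the largest rises in rRNA were at position 422 of 16S rRNA (rrsH), from 0.0452 ± 0.009 to 2.41 ± 0.507 stops per 1000 (SD, n = 3 each; 5.74 ± 0.73, log2, SE), position 140 of 23S rRNA (5.38 ± 0.78) and position 210 of 16S rRNA (5.24 ± 0.85). Position 392 of the thrU to rpoC operon rose by 6.24 ± 0.71 and position 2264 of yejL-yejM-proL, which carries a proline tRNA gene, by 3.86 ± 0.62. Position 141 of csrB rose by 4.81 ± 0.68, position 3281 of ffh-rpsP-rimM-trmD-rplS by 6.06 ± 0.98 and position 4228 of the ATP synthase operon by 5.69 ± 0.96. At position 3085 of the ribosomal protein operon that starts with rpsJ the frequency fell (-6.51 ± 0.85, log2, SE), from 17.4 ± 5.74 to 0.19 ± 0.0699 stops per 1000. With DMS it was also low there, at 0.256 ± 0.183 stops per 1000, so this fall is not particular to EDC. In edgeR 39 of 18953 positions passed, 38 higher and 1 lower, though 3093 of 6747 non-overlapping positions were higher, 2324 had an unadjusted p under 0.05, and 35.6% did not overlap between groups (chance gives 10%). None passed in ssrA, rnpB, ssrS or ffs, where 9, 17, 7 and 1 had an unadjusted p under 0.05, but 20, 28, 9 and 2 passed without DMS replicate 2, a library of neither group. The count changed with the libraries in the fit: it was 0 without any 1 control library or EDC replicate 3, 1 without EDC replicate 2, 9 without EDC replicate 1, 3501 without DMS replicate 2 (1770 higher, 1731 lower), 3325 with only the 2 groups in the fit (1669 higher, 1656 lower) and 1013 in DESeq2 (690 higher, 323 lower). With the replicate number as a block it was also 0. In fits of only the 2 groups compared, DMS against control had the lower count, 122 against 3325. The sizes of the DMS and EDC counts therefore cannot be ranked. Each of the 9 named positions lost its call without any 1 control and without EDC replicate 3 (adjusted p up to 0.305).

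Directly between reagents, position 1262 of 16S rRNA (8.13 ± 0.71), position 341 of 23S rRNA (7.32 ± 0.69) and position 1406 of 16S rRNA (6.83 ± 1.24) were higher with DMS (log2, SE). So were position 48 of rnpB (6.89 ± 1.08), position 154 of gcvB (7.01 ± 1.90, and 4.81 without DMS replicate 2) and position 5901 of the ybgC to lysQ operon (10.54 ± 1.31). Position 90 of csrB was higher with EDC (-6.55 ± 1.07). Positions without an EDC stop in the thrU to rpoC operon (9653), proB-proA-thrW (2641), fumA-fumC (2862), rbsD-rbsA-rbsC-rbsB-rbsK-rbsR (3030) and clpP-clpX-lon-hupB-ppiD (249) were at least 158.1-fold, 64.85-fold, 230.9-fold, 202.4-fold and 149.8-fold higher. In all 5 DMS replicate 2 held the most stops: without it the log2 fold changes at 9653, 2641 and 249 went from 10.18, 9.53 and 11.45 to 9.80, 5.53 and 9.04. At fumA-fumC and the rbs operon they went from 11.74 and 11.45 to 4.59 and 6.10, and the calls ended (adjusted p = 0.188 and 0.0545). The values at 2641, fumA-fumC and the rbs operon then lie below the bounds given, and 2641 passed narrowly (edgeR adjusted p = 0.0489). In edgeR 2423 of 18953 positions passed, 1548 higher and 875 lower with DMS, and 41.5% did not overlap (chance gives 10%), of which 3488 of 7873 positions were higher. In tmRNA 6 rose and 7 fell, in rnpB 16 and 5, in ssrS 5 and 2 and in ffs 1 and 1, and without DMS replicate 2 these were 20 and 30, 29 and 21, 11 and 5, and 5 and 1. With the replicate number as a block over all 9 libraries, which is no paired test of DMS and EDC alone, 450 positions passed. The calls at gcvB (adjusted p = 0.0552), proB-proA-thrW (0.0846), fumA-fumC (0.0583) and the rbs operon (0.106) ended. With 1 TMM factor per library 1990 were higher and 2221 lower. Without EDC replicates 1, 2 and 3 the count was 202, 142 and 160, without DMS replicate 3 it was 1557, and without DMS replicate 2 it was 6270 (3496 higher, 2774 lower). Of the 12 named positions 5 passed whichever library was left out (16S 1262, 23S 341, ybgC to lysQ 5901, rnpB 48 and csrB 90), and the others lost their call without any 1 EDC library (adjusted p up to 0.150).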

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

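Leaving out position 1, masking noncoding RNAs inside operons, capping positions at 10 stops, and leaving out DMS replicate 2 for EDC against control were chosen after seeing the data. Counts of stops at untargeted bases were not run, for lack of a genome sequence.

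Counts below are in the order DMS against control, EDC against control, DMS against EDC. For RNAs (18, 32 and 8) DESeq2 called 67, 61 and 70. Fits of the 2 groups alone gave 6 for the first, depth in place of stops gave 17 for the second, and leaving out position 1 gave 17 for the third. Capping gave 11, 19 and 19. Leaving out 1 library gave 8 to 22, 1 to 48 and 6 to 22.

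For positions (2298, 39 and 2423) DESeq2 called 4978, 1013 and 5033, a mean of at least 50 stops left 1385, 78 and 1517, and an offset from depth gave 4009, 13 and 3856. Fits of the 2 groups alone gave 122, 3325 and 363, and the replicate block gave 202, 0 and 450. A single TMM factor per library gave 512 for the second and 4211 for the third. Leaving out 1 library gave 62 to 5979, 0 to 3501 and 142 to 6270.

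Of gene lists that passed camera (1, 0 and 4) an estimated correlation left 0, 0 and 0, and leaving out 1 library gave 1 to 4, 0 to 1 and 2 to 5. The operon ompC-apbE-ada, not called with DMS, had a log2 fold change of -0.016 with depth and from -0.019 to 0.227 without 1 library. Over all named RNAs 53 uncalled values in 15 RNAs changed sign under an alternative, and 0 called values did. Of values of called RNAs 423 stayed past the threshold and 222 did not, and of called positions 255 stayed and 129 did not.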

Other observations

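The tests that leave out DMS replicate 2 or EDC replicate 1, that use depth for tRNA operons, that thin libraries, that use rRNA bases and that regroup libraries, and the RNAs of the next paragraph, were chosen only after the result was seen; the list of rRNA bases itself was written before any test of positions.

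Some RNAs outside the naming rule passed in both comparisons with the controls. The RNA of asparagine synthetase A, asnA, stood at 79.98 ± 7.61 CPM in controls, 460 ± 96.3 with DMS and 512 ± 137 with EDC (SD, n = 3 each), with edgeR adjusted p = 0.00228 and 0.00382. The small protein operon azuC-yecJ had log2 fold changes of 3.95 ± 0.51 with DMS and 2.51 ± 0.48 with EDC (SE). Both comparisons use the same control libraries, and no overlap was tested. The share of all stops in 16S rRNA was 16.05% ± 3.32 in controls, 13.8% ± 2.23 with DMS and 23.5% ± 0.627 with EDC (SD, n = 3 each), reported as values with no test.

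A hypothesis was that stops lie 1 base 3′ of bases that the probes modify. Bases at 289 rRNA positions were taken from textbook knowledge (universal 16S primer sites, 23S functional sites and 5S rRNA), not from the files, and the log2 stop frequency over the controls was compared between A and C (151 bases) and G and U (138 bases). With DMS, A and C exceeded G and U by 0.672 ± 0.0859 (SD, n = 3) at the position 1 base 3′, against 0.263 at most at the other shifts from -3 to 3. At shift -3, where this 0.263 lies, every DMS library was also above every control, with the same permutation p of 0.1, so separation and p are not particular to the position 1 base 3′ and only the size of the difference is. At shift 3 all DMS libraries were negative (-0.034, -0.307 and -0.0597), also with a permutation p of 0.1. With EDC, G and U exceeded A and C by 0.335 ± 0.0459 (SD, n = 3), while the other shifts ran from -0.182 to 0.0772. The -0.182 lay at shift -3, where all 3 libraries were negative (-0.151, -0.155 and -0.241, permutation p = 0.3). Treated libraries were set against the mean of all 3 controls and each control against the mean of the others. The permutations did not recompute these references, so their p-values are approximate. At the position 1 base 3′ each treated library lay above every control library in both cases (two-sided permutation p = 0.1, the smallest that 3 against 3 allows). These values are consistent with the hypothesis for both probes, though bases are not independent replicates.

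In the OxyR list, which passed fry (adjusted p = 0.000963) but lost its camera call with an estimated correlation (0.182), 6 of 9 RNAs were higher with DMS. The sparse library alone does not account for this, since without DMS replicate 2 all 9 members had a log2 fold change above 0 (median 1.09) and 5 were called, though the count of calls depends on the libraries in the fit and was 2 without EDC replicate 1. With each position capped at 10 stops the median log2 fold change of the list went from 1.49 to 1.06, with 9 of 9 members above 0. A cap on raw counts also lowers a fold that is spread evenly over well-counted positions. The fall therefore cannot tell whether a few heavily counted positions carry part of the rise. Stops at position 1, where cDNA reaches the annotated 5′ end, could be compared for 4 members and gave a median log2 ratio of 0.47. The ratio was 3.37 for oxyS, 0.92 for trxC-yfiP-yfiQ-pssA, 0.015 for dps and -2.025 for ybfE-fldA-uof-fur. Thus dps, higher by 3.36 over the whole RNA, had no such rise at position 1. Extra stops inside these RNAs and more RNA therefore cannot be told apart. A response of the cells to DMS stays an untested possibility.

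Of 27 tRNA operons 12 were higher with EDC, and 6 from the depth files, which may count a read once. Reads counted at several identical genes multiply control and EDC stops alike. Such counting makes no fold by itself, and the depth median of 1.64 is no test of it. It can repeat 1 change in several operons, so how many of the 12 are separate stays open. A first test without EDC replicate 1 gave a median of 1.22 with 1 operon called and did not decide, so the share of stops replaced it. EDC replicate 1 alone does not account for the higher tRNA share, since the lower share of the other EDC libraries was 32.8%, above the highest control at 21.9%. That share pools all operons, so it does not test the rise of each. Without EDC replicate 1, 23 of 27 operons had a log2 fold change above 0. Capped at 10 stops per position the median was 0.92, with all 27 operons above 0, and 3 operons passed. Since the cap also lowers an evenly spread fold, this cannot tell whether positions with very many stops carry part of the rise. Stops at position 1 could be compared for 6 of the 27 operons and gave a median log2 ratio of 1.88 with 5 above 0 (from -1.36 to 2.98). This does not decide between modification of tRNA by EDC and a change in tRNA amount, and both stay open. Higher values with EDC were not limited to these operons. The 3 rRNAs had a median log2 fold change of 0.99, with none called. The 26 other noncoding RNAs had a median of 0.041, with 1 called higher.

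DMS replicate 2 had a stop at 2.09% of non-rRNA positions. Its depth does not account for this, since the lowest of the 4 libraries that could be thinned to its 2349562 non-rRNA stops still had a stop at 15.6% of positions. Few starting molecules that were amplified many times are a possible explanation that no molecular identifier tests here.

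Regrouping 3 libraries against 3 makes 10 splits, too few for a share under 0.05. Calls of RNAs were 18, 32 and 8 in the real splits (DMS against control, EDC against control, DMS against EDC) and calls of positions 2298, 39 and 2423, and the highest of the other splits was 0 in each; the real split was the 1 with as many.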
